A study of Mus musculus with 48 samples.

How the data were processed

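RNA of the pars tuberalis was taken by punch from slices 0.5 mm thick with a needle of 0.5 mm, and each of the 48 arrays measured 1 pool of tissue. The design text states that 25 mice were pooled per time point and that the whole procedure was repeated to give the 2 replicates; nothing beyond the labels and that text says that the replicates are separate. No label says that 1 replicate number marks the same repeat in every group, and no block for it was used in the main model. The values show such a tie in some conditions: the difference between replicates 1 and 2 correlated across genes between time points with a median r of 0.238 under long days and 0.273 in delay, against 0.0328 under short days and 0.0698 in advance. Fits with a block for the replicate number, over all arrays and within each condition, were alternatives, the latter chosen after seeing the data. The log2 values used here are those the authors deposited: probe set summaries made by RMA in R 2.8.0, per the labels, with quartiles nearly equal across all 48 arrays. Background correction, quantile normalization and summary were therefore done before deposit and were not repeated. No pair of arrays held identical values. For arrays their number limits the precision, and here it is 2 per condition and time point.

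Of 45101 probe sets, 34958 carried 1 gene symbol in the probe annotation, 932 carried several and 9211 none. Of those with 1 symbol, 34754 had an Entrez identifier present in the RefSeq gene table, and no symbol was changed through it. Each gene was represented by its probe set with the highest mean over all arrays among those with 1 symbol, which gave 18193 genes, 9010 of them with more than 1 probe set. No filter on dim genes was used in the main model.

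A linear model with a mean for each of the 24 groups of 2 arrays was fitted to every gene with limma 3.58.1 in R 4.3.3, which left 24 residual degrees of freedom. Variances were moderated by empirical Bayes with a trend on the mean level, tests were two-sided, and p-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. A gene that passed had an adjusted p below that threshold, and errors of changes are SE from this model. The comparisons were long minus short days averaged over 6 time points, F tests for variation over the day in each photoperiod and for a difference in daily course matched by ZT, and the first-day contrasts. These were the change from ZT16 to ZT20 in advance minus that under short days, the change from ZT8 to ZT12 in delay minus that under short days, the difference of these responses, ZT12 and ZT16 minus ZT0, ZT4 and ZT8 in delay minus the same under short days, and advance minus delay at ZT0, ZT4 and ZT8. First-day arrays labelled ahead of the extra light, minus short-day arrays with the same labelled ZT, formed the contrast called age and run, in which clock phase differs as well. Which delay arrays precede that light was read from ZT, since their titles and ZT labels give a time and no day. Peak times came from a cosine with a period of 24 h.

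Comparisons, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined, and alternatives added later are named as chosen after seeing the data. The rule took the 10 largest rises and 10 largest falls with the same sign at every time point for the contrasts over several time points, the 5 largest of each for the 4 h contrasts and the age and run contrast, and the 10 smallest p-values for the F tests. It added Tshb, Cga, Eya3, Tef, Hlf, Dio2, Mtnr1a, the clock genes and up to 4 members of every other list with the smallest p-values. Clone names without a gene name were passed over. The text names only some of the genes the rule took, and which of these was decided after their values were seen. Besides the genes listed, the rule added 1 by name that is not reported here. Levels at single times of day that are described in the text were chosen among these genes after their values were seen.

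The 27 lists were thyrotropin and photoperiod, EYA and DACH family with their homeobox partners, clock, melatonin and cAMP signalling, immediate early, thyroid hormone handling, pars distalis, tanycyte, ependymal, hypothalamic neuron, oligodendrocyte, astrocyte, microglia and macrophage, endothelial, blood cell, meninges and fibroblast, choroid plexus, endoplasmic reticulum folding, heat shock and cold inducible, secretory granule, endocannabinoid, glucocorticoid responsive, angiogenesis, cell cycle, cholesterol synthesis, ribosomal protein and mitochondrial complex I genes. They were tested against all other genes with camera in limma, with a preset correlation between genes of 0.01 and again with a correlation estimated for each list, adjusted over the lists of a comparison.

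The phase of each array was read by matching its 15 varying clock genes to their short-day course, with a short-day array left out of the course it was matched to. Shifts were compared by two-sided permutation tests with 1e+05 resamples, adjusted over 5 comparisons. Only delay against advance is reported, since the genes and the course were taken from the short-day arrays. This reading was chosen after the data were seen. In simulated data 100 genes were changed by 0.5 and 100 by 1 on the log2 scale. The model found 100 and 100 in the comparison of long with short days and 19 and 87 in the 4 h response ahead of dawn. It found 21 and 89 in that after dusk and 4 and 47 in their difference, with 2 to 16 false calls per comparison. Values were drawn independently for each gene and array, without replicate ties or differences in RNA quality or tissue. The false calls therefore do not give the error rate in the real arrays. Alternatives covered scaling (cyclic loess, centring on the 75th percentile), a filter on dim genes, the choice of probe set, the variance model, array weights, the arrays fitted, a replicate block, covariates for tissue and RNA quality, baselines, and leaving out each array in turn. Sequence-level data and the raw array images were not analysed here.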

Results

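Messenger RNA was measured on 48 expression arrays of the mouse pars tuberalis, the tissue around the pituitary stalk that reads the melatonin signal of the night. The lighting regimes were chronic short days with 8 h of light, long days with 16 h of light for 2 weeks, and a first long day after 3 weeks of short days. On that first day the extra 8 h of light came either ahead of dawn (advance, lights on from ZT16 of the short-day cycle) or after dusk (delay, lights on until ZT16). Each of the 4 conditions was sampled at 6 time points, 4 h apart, with 2 arrays per time point and so 12 arrays per condition. ZT counts hours from lights-on, and in both first-day conditions it counts from lights-on of the earlier short-day cycle. The labels give an age of 8 weeks for both chronic conditions and 6 weeks for both first-day conditions, so any comparison across these ages also compares ages and sets of mice. The median log2 value of an array lay between 6.98 and 7.03. The arrays separated by condition, which accounted for 83.9% of the variance along the first principal component and 90.5% along the second.

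**Figure D1:**
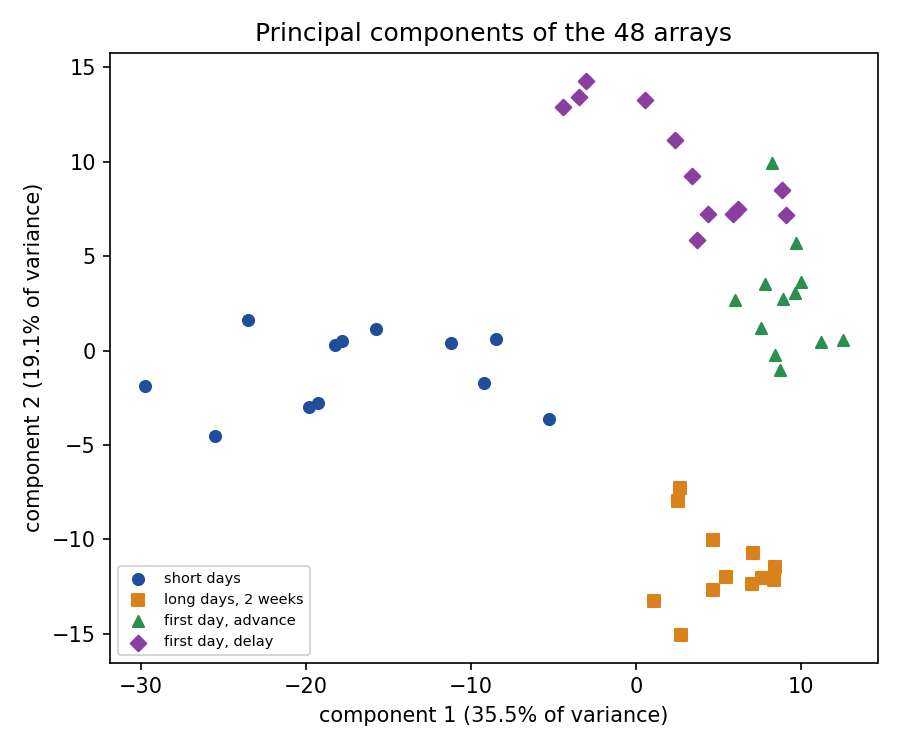
Scores of the 48 arrays on the first 2 principal components, which hold 35.5% and 19.1% of the variance, with 1 point per array coloured by condition. The short-day arrays lie apart from the other conditions along the first component, and long days lie apart from both first-day conditions along the second.

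The first comparison asks how the tissue differs after 2 weeks of long days. Tshb, the beta subunit of thyrotropin, was 11.8-fold higher under long days (log2 change 3.56 ± 0.16 SE, adjusted p = 3.58e-18, 12 arrays against 12). Its day mean was 14.09 against 10.54, and it was higher at all 6 time points. By the design text the whole procedure was repeated to give the 2 replicates, so 12 arrays are not 12 separate runs of a lighting regime. The p-values of this comparison rest on spread between the arrays of a time point. Dct, an enzyme of melanin synthesis, rose 5.22-fold, Lrat, which esterifies retinol, 3.45-fold, Ezh2, a histone methyltransferase, 2.95-fold, and Slco1c1, a thyroxine transporter, 2.83-fold. Dusp4, a phosphatase that acts on MAP kinases, rose with an SE of 0.13 from a day mean of 7.64 to 9.70, and Spink4 and Piwil4 rose 3.71-fold and 3.12-fold. Sval2 also rose, from a short-day level below the first quartile of the probe sets of every array, so no fold is given. The largest falls were smaller: Col23a1, a collagen, fell by 1.26 ± 0.04 on the log2 scale, Arhgef17, a guanine nucleotide exchange factor, by 1.18 ± 0.06, Lgr6, an R-spondin receptor, by 1.10 ± 0.05, and Slc25a23, a mitochondrial carrier, by 1.09 ± 0.08. Other probe sets, all of lower mean level, moved far less for Arhgef17 (-0.23 to -0.05), Lgr6 (-0.32) and Piwil4 (0.21, at a mean level of 4.55). Those of Col23a1 changed by -1.02 and -0.99.

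Among genes tied to the photoperiodic response, Eya3, a transcriptional co-activator, was 1.87-fold higher under long days (adjusted p = 9.07e-12), Dio2, the deiodinase that activates thyroid hormone, 2.02-fold (adjusted p = 1.38e-15), and Mtnr1a, a melatonin receptor, 1.87-fold (adjusted p = 1.99e-05). Mtnr1a did not pass in the arrays of either replicate number alone. Hlf, a transcription factor of the clock output, was 1.62-fold higher. Cga, the alpha subunit shared by thyrotropin and the gonadotropins, was 13.77 against 13.73, a change of 0.03 ± 0.06 that did not pass (adjusted p = 0.677). Of 12 measured thyrotropin and photoperiod genes, 6 rose and 2 fell, with the same counts adjusted over the list alone, and the list stood above other genes (camera adjusted p = 0.00525). With an estimated correlation its adjusted p was 0.629. Of 11 genes of the EYA and DACH families and their homeobox partners 4 rose, Six4 by 0.81 ± 0.08 and Eya1 by 0.77 ± 0.09 among them, and 5 fell (4 and 6 adjusted over the list alone), among them Six6, which fell by 0.59 ± 0.06. Of 12 thyroid hormone handling genes 4 rose and 3 fell: Hr, a nuclear co-repressor, rose by 0.67 ± 0.05, and Thra, a thyroid hormone receptor, fell by 0.41 ± 0.04. Of 22 melatonin and cAMP signalling genes 9 rose and 8 fell, and the inhibitory G proteins went apart, Gnai3 up by 0.53 ± 0.06 while Gnai2 fell by 0.42 ± 0.04. Of 22 clock genes 9 rose and 2 fell, with Rora up by 0.57 ± 0.06 and Cry2 by 0.36 ± 0.06. The last 4 lists had camera adjusted p between 0.0916 and 0.872.

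Genes of protein folding in the endoplasmic reticulum rose more often than they fell, 12 against 5 of 24 measured (12 and 6 adjusted over the list alone; camera adjusted p = 0.045, and adjusted p = 0.851 with an estimated correlation). Pdia4, a disulfide isomerase, rose by 0.64 ± 0.07, Sdf2l1 by 0.52 ± 0.05, and Hsp90b1, a chaperone, and Atf4, a stress transcription factor, each by 0.31 ± 0.04. Of 36 genes of mitochondrial complex I, 23 fell and 3 rose (24 and 3 adjusted over the list alone; camera adjusted p = 0.0288, and adjusted p = 0.918 with an estimated correlation), among them Ndufa10, which fell by 0.45 ± 0.04, and Ndufs7, which fell by 0.43 ± 0.05. Of 49 ribosomal protein genes 22 fell and 4 rose (camera adjusted p = 0.327). A sign of RNA quality moved with these groups: the signal of actin probes at the 3' end minus that at the 5' end was 1.65 ± 0.12 under long days against 1.90 ± 0.12 under short days (SD, 12 arrays each, log2 units). With that signal as a covariate, chosen after seeing the data, 5006 genes passed.

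Of the lists of markers of neighbouring cell types, none passed camera (lowest adjusted p = 0.104, for ependymal cells). Of 10 ependymal genes 5 fell and 0 rose, with Dynlrb2 and Tekt1, both parts of motile cilia, falling by 0.73 ± 0.07 and by 0.58 ± 0.05. Of 10 astrocyte genes 4 rose and 4 fell: Gjb6, a connexin, rose by 0.72 ± 0.06, while Slc1a3, a glutamate transporter, fell by 0.59 ± 0.03 and Gfap, an intermediate filament, fell by 0.88 ± 0.11. Of 24 hypothalamic neuron genes 4 rose and 6 fell, with Oxt, which encodes oxytocin, up by 0.95 ± 0.09 and Slc32a1, the vesicular GABA transporter, lower: it fell by 0.72 ± 0.07. Among 17 pars distalis genes 4 rose and 7 fell: Trhr, the receptor of thyrotropin-releasing hormone, rose by 0.81 ± 0.05, Fshb, the beta subunit of follicle-stimulating hormone, fell by 0.93 ± 0.16, and Prl, which encodes prolactin, rose by 1.74 ± 0.59 (adjusted p = 0.014). Prl did not pass once short-day ZT12 replicate 2 or long-day ZT8 replicate 1 was left out. Arrays with Gh or Prl above a log2 level of 10, hormones of the pars distalis, numbered 3 under long days and 1 in each other condition. Tanycyte genes (7 up and 4 down of 15), meninges and fibroblast genes (5 and 3 of 12), oligodendrocyte genes (4 and 3 of 12, with Mobp up by 0.60 ± 0.05) and choroid plexus genes (2 and 2 of 9) moved both ways. Microglia and macrophage genes (2 up and 5 down of 11, with Csf1r falling by 0.28 ± 0.04) and endothelial genes (1 and 4 of 11, with Plvap falling by 0.52 ± 0.05) fell more often. Of 8 blood cell genes 0 passed, against 8502 of all 18193 genes in limma (9397 at an unadjusted p under 0.05).

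Other lists also moved both ways under long days. They were secretory granule genes (2 up and 7 down of 15, Chga up by 0.26 ± 0.05 and Pam, an amidating enzyme, falling by 0.71 ± 0.05), heat shock and cold inducible genes (2 and 3 of 10, Cirbp up by 0.82 ± 0.09 and Hspa1a falling by 0.58 ± 0.08), and immediate early genes (3 and 5 of 25). Endocannabinoid genes (3 and 6 of 11), glucocorticoid responsive genes (4 and 2 of 15), angiogenesis genes (6 and 3 of 14), cell cycle genes (5 and 2 of 17) and cholesterol synthesis genes (5 and 3 of 15) did so as well. Adjusted over the list alone, the counts of the lists above given with 1 pair of counts were the same, except for oligodendrocyte (5 up and 3 down), microglia and macrophage (2 and 6), immediate early (3 and 4) and endocannabinoid genes (4 and 6). Median, mean and camera direction differed in sign in 8 of the 27 lists. In the test across all genes 8502 of 18193 passed, 3200 higher and 5302 lower. Most changes were small, with 382 genes changed at least 1.5-fold and 41 at least 2-fold (33 up and 8 down). Fitted to the arrays of each replicate number alone, 4581 and 5337 genes passed, 3537 in both with the same sign against 710.1 expected of independent lists, and 3 with opposite signs.

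The next question is whether the course over the day differed between short and long days. Neurod1, a basic helix-loop-helix transcription factor, stood at 9.22 ± 0.27 (SD, n = 2) at short-day ZT16 and at 6.19 to 6.32 at ZT0, ZT4, ZT12 and ZT20, whereas its long-day levels lay between 6.70 and 7.27. Vegfd, a growth factor of lymphatic vessels, ranged from 7.94 at ZT8 to 10.07 at ZT20 under short days and from 8.49 to 9.21 under long days. Dio2 and Mtnr1a peaked at ZT12 under short days, at 13.13 ± 0.22 and 9.35 ± 0.40 (SD, n = 2), and Dio2 stayed between 13.47 and 13.65 under long days. Under long days several immediate early genes stood highest at ZT0, the time of lights-on: Btg2, an antiproliferative factor, at 11.27 ± 0.15, Gadd45b, a stress response gene, at 9.96 ± 0.06, Junb at 8.20 ± 0.11, Egr1 at 11.97 ± 0.12 and Gem at 9.06 ± 0.10 (SD, n = 2 each). At short-day ZT0 Junb was at 6.54 ± 0.16 and Egr1 at 10.38 ± 0.16, and under short days Egr1 was highest at ZT20, at 11.25 ± 0.03 (SD, n = 2 each). By the sample titles, short-day ZT20 and long-day ZT0 fall at the same clock time. Fst, which encodes follistatin, was at 8.79 ± 0.15 at long-day ZT0 and between 5.70 and 6.66 at the other times.

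Clock genes varied over the day in both photoperiods, 15 of 22 under short days and 13 of 22 under long days (15 in each adjusted over the list alone), and 14 of 22 differed in their daily course (16 adjusted over the list alone). Per2, a repressor of the clock, peaked at ZT 8.27 under short days and later, at ZT 16, under long days, from a 24 h cosine. The peaks of Nr1d1, also a repressor, were at ZT 1.2 and ZT 9.3, those of Dbp, a clock output factor, at ZT 3.18 and ZT 12, those of Arntl, an activator of the clock, at ZT 18.6 and ZT 2.37, and those of Cry1 at ZT 14.2 and ZT 20.9. Read against the short-day course of 15 clock genes, long-day arrays stood a mean of -7.86 h from their labelled ZT (SD 1.89, n = 12) and short-day arrays -0.025 h (SD 0.564, n = 12). The genes and the course come from the short-day arrays, so their shift near 0 and its small spread are partly set by the method, and no test against them is given. Lights went off at ZT8 under short days and ZT16 under long days. By the sample titles and ZT labels, lights came on 4 h earlier in clock time under long days than under short days and in delay. Of the long-day shift, in the arrays and in the peaks, 4 h therefore comes from how ZT is counted. Its size in hours can be set beside that of the delay arrays only after those 4 h are taken off. Of 25 immediate early genes 10 varied under long days (13 adjusted over the list alone) and 8 under short days (9 adjusted over the list alone), and of 12 meninges and fibroblast genes 8 varied under short days (11 adjusted over the list alone), Col3a1, a collagen, among them (adjusted p = 1.85e-06).

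Across all genes 1621 varied under short days, 296 under long days, and 782 differed in course. Matched by clock time in place of ZT, 85 genes differed in course. With a block for the replicate number in each condition, chosen after seeing the data, 2838 genes varied under short days, 439 under long days, and 1265 differed in course. The counts rested on single arrays: for short days they ran from 901 without ZT12 replicate 2 to 2765 without ZT16 replicate 1, and for the difference in course from 499 without long-day ZT12 replicate 1 to 1456 without short-day ZT16 replicate 1. Of the long-day arrays, ZT16 replicate 2 and ZT20 replicate 2 stood -3.7 h and -12.1 h from their labels, and with their labels exchanged 492 genes varied under long days.

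**Figure D2:**
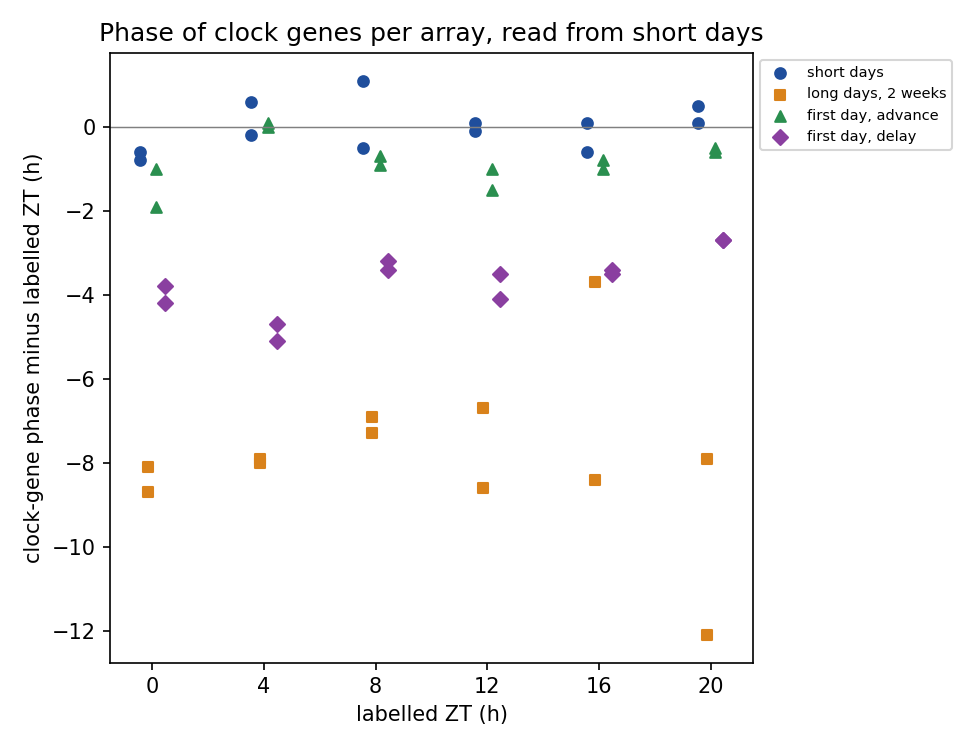
Phase of 15 clock genes in each array, read from the short-day course, minus the labelled ZT, in hours, with 1 point per array. Short-day arrays lie between -0.8 h and 1.1 h, delay arrays between -5.1 h and -2.7 h, and long-day arrays around -7.86 h with the ZT16 and ZT20 replicate 2 arrays at -3.7 h and -12.1 h. Long-day ZT is counted from a clock time 4 h earlier than short-day or delay ZT, which makes up 4 h of the long-day shift.

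What did the first 4 h of light ahead of dawn do? From ZT16 to ZT20, in light in the advance condition and in darkness under short days, Pde10a, a phosphodiesterase of cyclic nucleotides, rose 4.29-fold more in the light (log2 2.10 ± 0.24 SE, adjusted p = 3.34e-06, 2 arrays in each of 4 groups). Fst rose 3.76-fold, Hhip, an inhibitor of hedgehog signalling, 3.38-fold, Rorb, a nuclear receptor, 3.11-fold, and Eya3 3.06-fold (adjusted p = 0.000685). Crem, a transcription factor of cAMP signalling, rose 2.53-fold, Slco1c1 2.38-fold, Dio2 2.10-fold, Nrp2, a co-receptor of vascular growth factors, 2.04-fold, and Trhr 1.93-fold. Vegfd fell by 1.73 ± 0.25, Klhl41, a kelch protein, fell by 1.44 ± 0.22, Kcnmb2, a potassium channel subunit, fell by 1.11 ± 0.24, and Pdzph1 fell by 1.07 ± 0.22. Gata2, a transcription factor, fell by 0.91 ± 0.19. A second probe set changed by -0.22 for Kcnmb2 and by -0.51 for Gata2, and the other probe sets of Vegfd changed by -1.60 and -1.71. Tshb itself changed by 0.30 ± 0.55 (adjusted p = 0.947).

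Of the fixed lists, 2 of 22 melatonin and cAMP signalling genes rose (3 adjusted over the list alone) and 2 of 12 thyroid hormone handling genes (2 adjusted over the list alone). Of 36 complex I genes 0 passed in limma, against 40 of all 18193 genes, so hardly any were to be expected in a list of that size. At an unadjusted p under 0.05 in limma there were 1128 of all genes. The complex I list was the only one to pass camera, downward (adjusted p = 0.00427, and adjusted p = 0.852 with an estimated correlation). In all, 33 genes rose and 7 fell. Without the array of short-day ZT16 replicate 1 the count was 334, and without advance ZT20 replicate 2 it was 18, with 26 without short-day ZT20 replicate 2 and 21 without advance ZT16 replicate 2. Fst did not pass without short-day ZT20, advance ZT16 or advance ZT20 replicate 2, and of the other genes named here Kcnmb2, Pdzph1, Gata2, Dio2, Slco1c1 and Trhr also failed without at least 1 array. Later in the advance day, measured in the same way from ZT16, 0 genes passed at ZT0, 1 at ZT4, 2 at ZT8 and 0 at ZT12 in limma. Over ZT0, ZT4 and ZT8 together 0 passed and 1679 had an unadjusted p under 0.05. Hhip passed at ZT8 (1.24 ± 0.21, adjusted p = 0.00871). From ZT16 to ZT12 within the advance day Eya3 was up by 1.26 ± 0.18, with 1.09 ± 0.26 after the short-day change was taken off (adjusted p = 0.391).

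The matching question for light after dusk used ZT8 to ZT12, by its labels lit in the delay condition and dark under short days. Here 7 genes passed and all 7 rose. Gpr6, an orphan receptor, rose 2.64-fold (1.40 ± 0.28 SE, adjusted p = 0.0489, 2 arrays in each of 4 groups), Fkbp5, a glucocorticoid-induced chaperone partner, 2.08-fold, Cables1 1.94-fold, Noct, a circadian phosphatase, 1.85-fold, and Fam107a 1.67-fold (adjusted p = 0.00855). Without subtraction of ZT8, delay ZT12 against short-day ZT12, Gpr6 turned to -0.19 and did not pass. Fkbp5 is also high at ZT8 under short days, at 10.30 ± 0.06 against 10.48 ± 0.15 at delay ZT12 (SD, n = 2). Clock genes of the delay arrays stood a mean of -3.69 h from their labels (SD 0.732, n = 12), and at ZT0 to ZT8, by the labels ahead of the extra light, -4.07 h (SD 0.742, n = 6). The count fell to 1 under cyclic loess and to 0 without short-day ZT8 replicate 1, short-day ZT12 replicate 1, delay ZT8 replicate 2 or delay ZT12 replicate 1, with 3 without short-day ZT12 replicate 2 and 4 without delay ZT8 replicate 1. It was also 0 without the arrays with high Gh or Prl, a choice made after seeing the data, and 1380 genes had an unadjusted p under 0.05 in limma.

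Set directly against each other, the change from ZT16 to ZT20 in advance and that from ZT8 to ZT12 in delay, each minus short days, differed for 29 genes. By the labels these are the first 4 h of light ahead of dawn and after dusk. By their clock genes the delay arrays stood at 4.8 h and 4.6 h at ZT8 and at 8.5 h and 7.9 h at ZT12, so if their labels are late this step holds no extra light, and a difference in clock time is not separated from one in light. The change was larger in advance for Fst by 2.45 ± 0.54 (adjusted p = 0.0437), Rorb by 2.25 ± 0.29, Cldn7, a tight junction protein, by 2.02 ± 0.39, Pde10a by 2.01 ± 0.34, Hhip by 1.86 ± 0.29, Crem by 1.57 ± 0.30, Trhr by 1.24 ± 0.26 and Nrp2 by 0.83 ± 0.17. The opposite held for Gpr6 and Fgf18, a fibroblast growth factor (difference -1.84 for each), Fkbp5 (-1.45 ± 0.28), Zfp418 (-1.41 ± 0.30) and Kcnk3, a potassium channel (-1.32 ± 0.27). Eya3 differed by 1.42 ± 0.37, which did not pass (adjusted p = 0.147), nor did Dio2 (adjusted p = 0.3) or Slco1c1 (adjusted p = 0.277). Of the 29 genes 51.7% were positive, and 72.7% of 33 under cyclic loess and 73.1% of 26 under 75th percentile centring. Leaving out 1 array moved the count from 10, without short-day ZT8 replicate 1 or ZT16 replicate 2, to 111, without short-day ZT16 replicate 1. Rorb, Pde10a and Hhip passed without each array, and each of the other 10 genes named above that passed failed without at least 4 of the 16 arrays.

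**Figure D3:**
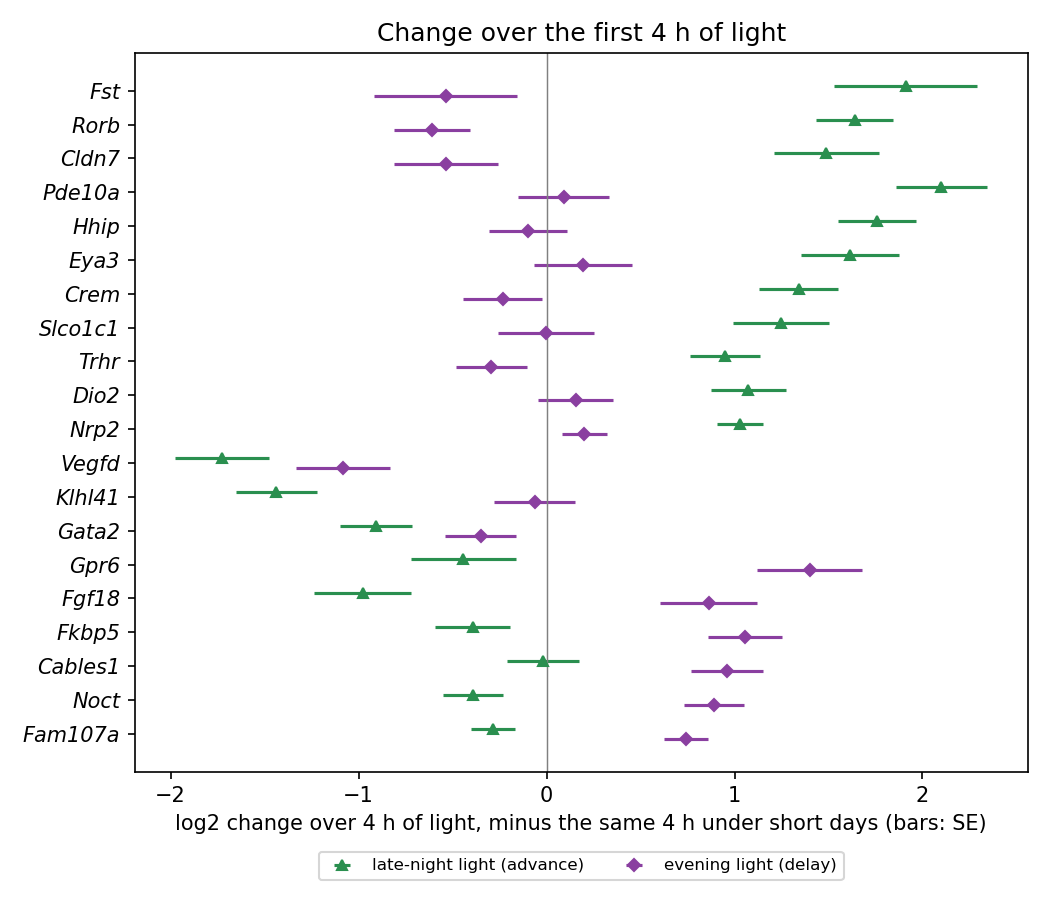
Log2 change over the first 4 h of light minus the change over the same 4 h under short days, with SE bars. The 20 genes were named for either response or for their difference. Each estimate rests on 2 arrays in each of 4 groups. Pde10a moved by 2.10 ahead of dawn against 0.09 after dusk, and Fkbp5 by -0.39 against 1.06.

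Over what the labels give as 4 to 8 h of light after dusk (ZT12 and ZT16 against ZT0 to ZT8, delay minus short days), Per2 was higher by 1.14 ± 0.13 SE (adjusted p = 9.38e-06, 20 arrays), Dbp by 1.12 ± 0.22, Tspan4 by 1.08 ± 0.13, Timeless by 1.06 ± 0.16 and Ciart, a clock repressor, by 1.06 ± 0.19. Arntl fell by 0.70 ± 0.14, Npas2, another clock gene, fell by 0.72 ± 0.12 and Vegfd fell by 1.23 ± 0.16. Without subtraction of the earlier times Vegfd turned to 0.13 and did not pass. Of 22 clock genes 9 rose and 3 fell (12 and 5 adjusted over the list alone), and the delay arrays were already behind their labels in clock phase at ZT0 to ZT8, by the shift of -4.07 h. The largest falls included Rtp4 (-1.33 ± 0.37), Oasl2 (-1.17 ± 0.35) and Ifi47 (-0.97 ± 0.22). None of these 3 passed without short-day ZT4 replicate 1, short-day ZT12 replicate 1, delay ZT12 replicate 1 or delay ZT16 replicate 1. Of 49 ribosomal protein genes 23 rose and 0 fell (36 and 1 adjusted over the list alone; camera adjusted p = 6.61e-10, and adjusted p = 0.484 with an estimated correlation), Rps26 by 0.39 ± 0.10 among them. Of 36 complex I genes 12 rose and 0 fell (29 and 0 adjusted over the list alone; camera adjusted p = 3.02e-09, and adjusted p = 0.484 with an estimated correlation), Ndufa2 by 0.42 ± 0.10 among them, which turned to -0.09 without subtraction of the earlier times. Under cyclic loess 0 genes of both lists passed, and under 75th percentile centring 1 ribosomal protein gene fell and 0 rose. Of 15 glucocorticoid responsive genes 5 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.00858), as did 1 of 10 ependymal genes (7 adjusted over the list alone; camera adjusted p = 0.0145), while 0 of 12 oligodendrocyte genes passed (camera adjusted p = 0.0377). With an estimated correlation these 3 had adjusted p of 0.484, 0.484 and 0.541.

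This comparison counted 1111 genes, 938 higher and 173 lower. The 3' minus 5' signal of actin moved with it: at ZT12 and ZT16 against ZT0 to ZT8 it was 1.9 ± 0.159 against 1.8 ± 0.128 in delay and 1.85 ± 0.0593 against 1.94 ± 0.152 under short days (SD, 4 arrays against 6). With that signal as a covariate, chosen after seeing the data, 86 genes passed. Under cyclic loess 80 genes passed, 48.8% of them higher, and under 75th percentile centring 287, of which 71 were higher, against 84.4% in the main result; with a block for the replicate number in each condition it was 2388, and the count ran from 139 without short-day ZT4 replicate 1 to 2631 without short-day ZT4 replicate 2. Of 100 regroupings of these arrays 8 gave as many genes, so chance is not excluded as the source of the count. The contrast takes off the steady difference between delay and short days, and uneven regroupings bring it back. They therefore cannot decide whether chance gave the count.

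Light that began ahead of dawn was also followed for 8 to 16 h by setting advance against delay at ZT0, ZT4 and ZT8, when delay mice had met no extra light by their labels. Tshb was 1.6-fold higher in advance (0.68 ± 0.22 SE, 6 arrays against 6) and did not pass (adjusted p = 0.0531). Dio2 was higher by 0.71 ± 0.08 (adjusted p = 8.61e-07), Slco1c1 by 0.58 ± 0.10, Cga by 0.57 ± 0.08 and Dct by 0.92 ± 0.14. Tmem178b, a membrane protein, was higher by 1.03 ± 0.13, Rbfox2, a splicing factor, by 0.90 ± 0.10, Prkar1a, a regulatory subunit of protein kinase A, by 0.76 ± 0.13, and Zbtb16, a glucocorticoid-induced zinc finger protein, by 0.85 ± 0.14. Vegfd fell by 1.35 ± 0.10 and Tafa3, a secreted protein, fell by 1.04 ± 0.16. Of the clock genes, Per2 was higher by 0.38 ± 0.08 and Npas2 fell by 0.48 ± 0.07. Several of these directions depended on the baseline and time point. Against short days Vegfd turned to 0.01, Tafa3 to 0.31 and Npas2 to 0.08. A further baseline, a choice made after seeing the data, was advance ZT16, with the same change under short days taken off. With advance ZT16 as its own baseline in this way, Tafa3 turned to 0.07, Npas2 to 0.12, Per2 to -0.31 and Tmem178b and Prkar1a each to -0.18. At ZT0 alone Per2 turned to -0.03 and Zbtb16 to -0.007, and at ZT8 alone Npas2 turned to 0.08. Of these turned values none passed. With advance ZT16 as its own baseline Dio2 was higher by 0.29 ± 0.16, Slco1c1 by 0.48 ± 0.21, Cga by 0.08 ± 0.16 and Dct by 0.61 ± 0.27. Those values kept their direction and did not pass. The clock phase at ZT0 to ZT8 was -0.733 h from the labels in advance and -4.07 h in delay (6 arrays each). Over all 12 arrays of each condition it was -0.817 h and -3.69 h (difference -2.88 h, two-sided permutation test, p = 1e-05, the smallest its resamples can give, adjusted p = 2.5e-05 over 5 comparisons). That test shuffles single arrays, and 12 arrays are not 12 separate runs of a lighting regime. Its p-value therefore does not measure the spread between runs.

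In this contrast 7 lists passed camera with the preset correlation, and 0 with an estimated one. Of 22 melatonin and cAMP signalling genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00235). Of 15 secretory granule genes 5 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 1.11e-05), Chgb by 0.31 ± 0.06 among them. Of 24 endoplasmic reticulum folding genes 5 rose and 0 fell (9 and 1 adjusted over the list alone, camera adjusted p = 2.27e-05). Glucocorticoid responsive genes rose in 7 and fell in 1 of 15 cases (8 and 2 adjusted over the list alone, camera adjusted p = 0.000141). Cell cycle genes rose in 2 and fell in 0 of 17 (7 and 0 adjusted over the list alone, camera adjusted p = 6.43e-05). Meninges and fibroblast genes rose in 3 and fell in 0 of 12 (5 and 0 adjusted over the list alone, camera adjusted p = 1.11e-05), Col3a1 by 0.57 ± 0.08 among them. Oligodendrocyte genes stood lower, 3 of 12 with 0 up (4 and 0 adjusted over the list alone, camera adjusted p = 0.00618), and Mobp fell by 0.38 ± 0.07. With an estimated correlation the adjusted p of these lists, in this order, were 0.131, 0.101, 0.141, 0.222, 0.0956, 0.199 and 0.516. The 3' minus 5' signal of actin was 1.69 ± 0.09 in advance and 1.85 ± 0.13 in delay (SD, 12 arrays each). Prl fell by 2.66 ± 0.83 and passed without only 1 of the 12 arrays, delay ZT0 replicate 1. Against short days Dusp4, which fell by 0.65 ± 0.18, reversed to 0.89 and passed, while Prl turned to 0.26 and Chgb to -0.02, which did not pass. Vgf, another secretory granule gene, which was higher by 0.49 against delay, reversed to -0.22 and passed. With advance ZT16 as its own baseline Dusp4 turned to 0.49 and Col3a1 to -0.21, and neither passed.

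In all, 1592 genes passed, 1007 higher and 585 lower, and 63.3% were higher against 45.2% under cyclic loess and 44.1% under 75th percentile centring. The count was 29, 65 and 378 at ZT0, ZT4 and ZT8 alone, 7948 with short days as the baseline, 0 with advance ZT16 as its own baseline, 934 with the actin signal as a covariate, and 825 without advance ZT0 replicate 1.

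**Figure D4:**
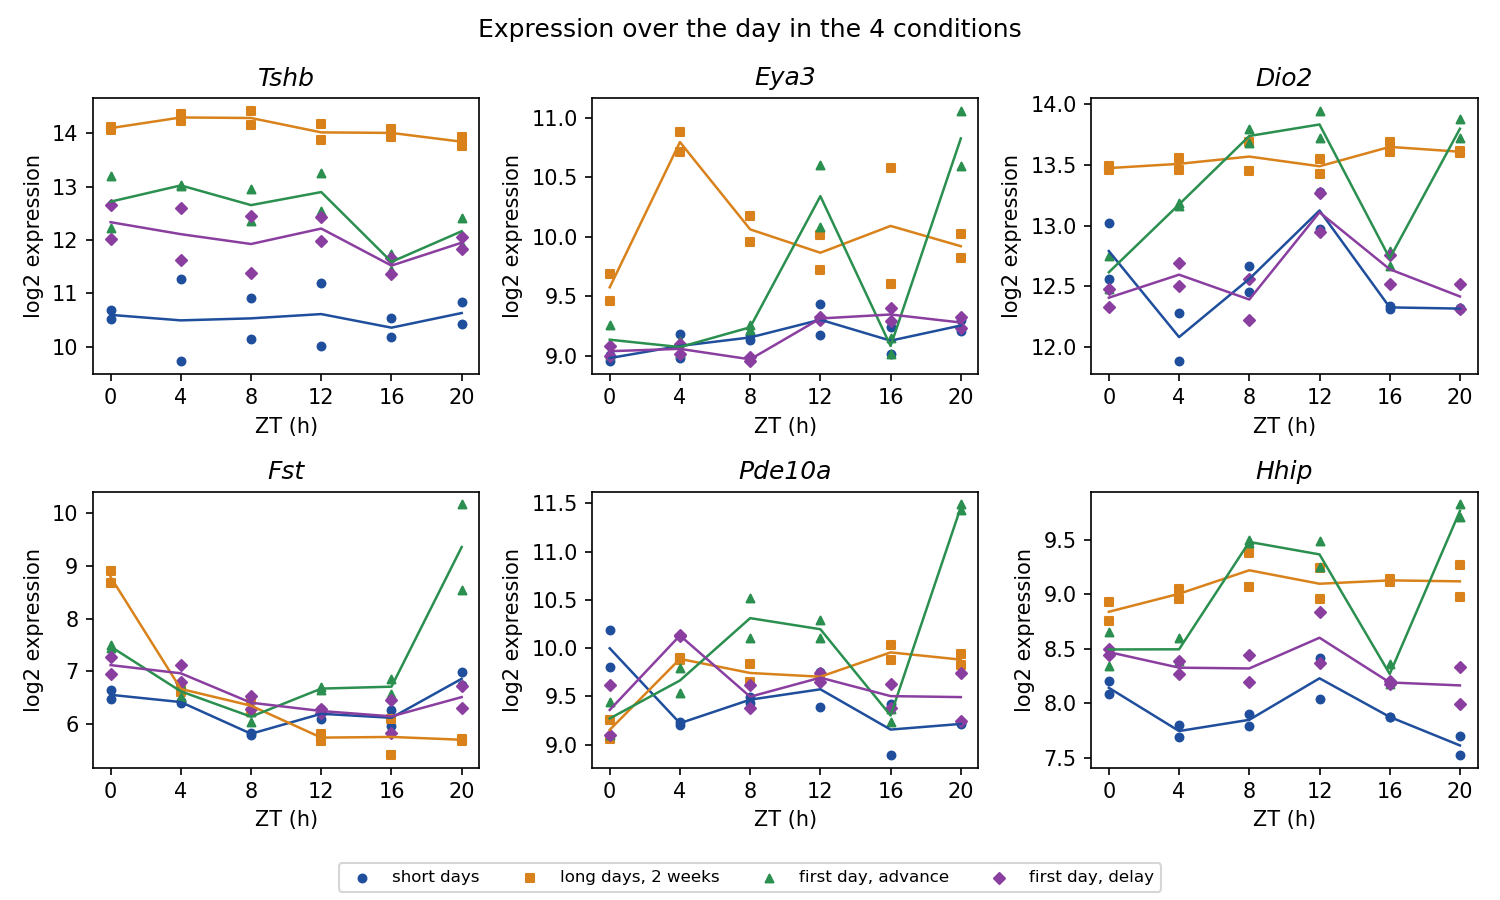
Log2 level of 6 genes against ZT in hours, with 1 point per array (2 per condition and time point) and lines through the means. Tshb has day means of 10.54 under short days, 12.01 in delay, 12.51 in advance and 14.09 under long days, and Eya3, Fst, Pde10a and Hhip stand high at advance ZT20.

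Do genes that differ after 2 weeks of long days already differ on the first day? Of the genes past the chronic comparison, 903 also passed advance against delay at ZT0 to ZT8 in the same direction, 591 higher and 312 lower, against 347.6 expected of independent lists, while 168 went the opposite way. Dct, Piwil4 (0.92 ± 0.18 on the first day), Slco1c1 and Dio2 are among those higher in both. The changes correlated across genes (r = 0.33), and genes are not independent replicates. Both comparisons share the direction of the actin signal, and with that signal as a covariate 362 genes were shared, against 119.4 expected, with r = 0.178 across genes. With advance ZT16 as its own baseline 0 first-day genes passed, so an overlap could not be counted, and r across genes was 0.1895. Of the 33 genes that rose within 4 h of light ahead of dawn, 22 were also higher after 2 weeks (5.8 expected), Eya3, Hhip, Crem, Slco1c1, Dio2 and Trhr among them. That correlation was 0.248 across genes, and with no change in any group 100 simulations of the shared arrays gave -0.0374 to 0.0597. The weights of the shared arrays cancel and noise was drawn independently for each gene, so this narrow range was set in advance. It does not show how far r can stray when genes are correlated.

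The last comparison has no difference in light by the labels. Arrays of delay at ZT0, ZT4 and ZT8 and of advance at ZT16 precede the extra light by their labels, and they were set against short days at the same times (8 arrays against 8), which asks what age, weeks under short days and run add. Of the 8 first-day arrays 6 are delay arrays, whose clock genes stood -4.07 h from their labels, so clock phase differs in this contrast as well, and light may differ if those labels are late or an earlier evening was lit. Tshb was 2.82-fold higher in them (SE 0.19 on the log2 scale, adjusted p = 1.4e-07), Prl 5.67-fold, Dusp4 2.39-fold, Tmc4 2.38-fold and Eya1 2.26-fold. At advance ZT16 alone, Tshb was higher by 1.23 ± 0.39 (adjusted p = 0.0272), and Dusp4 by 0.40 ± 0.32, which did not pass. Lncpint, a noncoding RNA, fell by 1.39 ± 0.16, Rap2b, a small GTPase, fell by 1.27 ± 0.09, Dlgap2, a synaptic scaffold, fell by 1.24 ± 0.10 and Zbtb7a and Nell2 each fell by 1.19 ± 0.18.

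Of 36 complex I genes 30 fell and 0 rose (30 and 0 adjusted over the list alone; camera adjusted p = 5.04e-10), Ndufs7 by -0.72 ± 0.06 among them. Of 49 ribosomal protein genes 36 fell and 2 rose (37 and 2 adjusted over the list alone; camera adjusted p = 2.99e-07), Rpl19 by -0.51 ± 0.06. Hypothalamic neuron genes fell as well, 13 of 24 with 0 up (13 and 0 adjusted over the list alone; camera adjusted p = 0.00603), Sst, which encodes somatostatin, by -0.99 ± 0.09, Slc32a1 by -0.84 ± 0.08 and Npy, which encodes neuropeptide Y, by -0.79 ± 0.08. So did 9 of 15 secretory granule genes with 0 up (9 and 0 adjusted over the list alone; camera adjusted p = 0.00172), Pam by -0.69 ± 0.06 and Vgf by -0.64 ± 0.08. Meninges and fibroblast genes rose, 7 of 12 with 0 down (7 and 0 adjusted over the list alone; camera adjusted p = 0.0395). With an estimated correlation the adjusted p of each of these 5 lists was 0.623. A sign of RNA quality moved with this contrast: the signal of GAPDH probes at the 3' end minus that at the 5' end was 1.935 ± 0.0836 in the first-day arrays and 2.299 ± 0.1448 in the short-day arrays (SD, 8 arrays each, log2 units), and no fit with it as a covariate was made. In all, 8871 genes passed, 3961 higher and 4910 lower, so 44.7% were higher, against 6830 of 10248 under 75th percentile centring. With pars distalis and neuron marker means as covariates 4077 genes passed, Prl not among them, and at advance ZT16 alone 3050.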

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

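The tests of exchanged labels, pars distalis or neuron tissue, age, evening light, time labels, RNA integrity, normalization and run were chosen after the results were seen, while the regroupings of arrays were planned.

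The change from ZT16 to ZT20 in advance differed from that from ZT8 to ZT12 in delay, each minus short days, by a direct test, for the 15 genes below. By the labels these are 4 h of light ahead of dawn and after dusk. The delay step lies about 4 h earlier by its clock genes, as weighed below, so a difference in light timing was not separated from one in clock time, for Fkbp5 among others, which is high at short-day ZT8 already. The difference, on the log2 scale, was positive for Fst (2.45), Rorb (2.25), Cldn7 (2.02), Pde10a (2.01), Hhip (1.86), Crem (1.57), Trhr (1.24) and Nrp2 (0.828). It was negative for Gpr6 (-1.84), Fgf18 (-1.84), Fkbp5 (-1.45), Zfp418 (-1.41), Kcnk3 (-1.32), Noct (-1.28, adjusted p = 0.00603) and Fam107a (-1.03, adjusted p = 0.00256). Noct and Fam107a lie outside the naming rule for this comparison and were chosen after their values were seen. Rorb, Pde10a and Hhip passed under every alternative and without each array, whereas Fst did not pass without 15 of the 16 arrays left out singly.

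A pair of long-day arrays, ZT16 replicate 2 and ZT20 replicate 2, stood out of place in the daily profile. Over 1606 genes that vary over the short day and lie outside the clock list, the step from ZT16 to ZT20 in replicate 1 correlated with that in replicate 2 at -0.507, and genes are not independent replicates. The 5 other long-day steps gave 0.362 to 0.643, and the same step gave 0.443, 0.769 and 0.485 under short days, in advance and in delay. With pars distalis and neuron marker means removed the value was -0.428, which argues against pars distalis or neuron tissue in the punches, and other neighbouring tissue was not tested. An exchange of the labels of this pair stays a candidate explanation, and no biological explanation was tested.

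Clock genes of the delay arrays stood about 4 h behind their labels. Advance arrays, from mice of the same labelled age, were shifted by -0.817 h, which argues against age. Delay arrays at ZT0, ZT4 and ZT8 were already shifted, by -4.07 h. If they were sampled ahead of the evening light of the labelled day, that argues against this light. Their titles and ZT labels give a time and no day, so the order was read from ZT alone. At ZT12, ZT16 and ZT20 the shift was -3.32 h, so time labels late by 1 step may explain it (read from genes outside the clock list the delay arrays ranged from -7.5 h to -0.1 h, which is no uniform lag), as may an evening of extra light on an earlier day, which was not tested.

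Many genes differed by small amounts between conditions, 8502 of them between long and short days, to which the tests of RNA integrity and normalization are limited. With the actin 3' minus 5' signal as a covariate 4813 of these passed still, which argues against RNA integrity, as read from actin, as the whole cause. Under cyclic loess 7899 did, which argues, for these genes, against scaling differences of the kind that step removes. It was laid over values already quantile normalized before deposit, so that first normalization was not tested and stays open. For light after dusk at ZT12 and ZT16 cyclic loess gave 80 genes against 1111, so there the later scaling stays open as well. The contrast of first-day arrays labelled ahead of the extra light with short days counted 8871 genes, and 6 of its 8 first-day arrays are delay arrays with clock genes at -4.07 h. For genes with small differences between first-day and chronic conditions, age or run therefore cannot be told apart from light or clock phase by that count. At advance ZT16 alone, where clock genes stood at -0.9 h (2 arrays), many genes still differed from short days, as counted above. There age or run is not mixed with extra light by the labels, or with a clock shift like that of delay. Long and short days share their labelled age, and whether they share a run is not given in the sources used here. Photoperiod stays open as the biological explanation between them.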

How the results depend on the processing

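The replicate block per condition, the actin covariate, leaving out arrays with high Gh or Prl, exchanged labels, advance ZT16 as its own baseline, advance ZT16 alone, other genes for the clock phase and simulations of shared short-day arrays were tests chosen after the data were seen. Of the values of genes named for long against short days, 1169 of 1174 under other settings and 1174 of 1176 without 1 array kept direction and side of the threshold. First-day comparisons were less stable under other settings. For 4 h of light after dusk 35 of 75 values kept direction and side of the threshold, and for ZT12 and ZT16 219 of 326 did. For advance against delay 379 of 491 did, with 25 reversed, and for the difference of the 4 h responses 136 of 179. The cause was not tested for any change below, except that fits with fewer arrays or a single time point hold fewer samples.

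Light after dusk for 4 h (7 genes) gave 1 gene under cyclic loess, 2 under 75th percentile centring, 3 with the mean of probe sets, 1 with all probe sets, 1 without the variance trend, 1 with only the arrays compared, 1 with tissue covariates, 11 with a replicate block per condition, 0 without arrays high in Gh or Prl and 825 without subtraction of ZT8, where Gpr6 reversed to -0.19. Light after dusk at ZT12 and ZT16 (1111) gave 80 under cyclic loess, 287 under 75th percentile centring, 505 with the mean of probe sets, 630 with all probe sets, 181 with array weights, 39 with only the arrays compared, 1837 with a replicate block, 2388 with a block per condition, 93 with tissue covariates, 86 with the actin covariate, 56 without arrays high in Gh or Prl and 3386 without subtraction of the earlier times. In the last, Vegfd reversed to 0.13, Gbp3 to 0.0693, Rpl6 to -0.0344 and Ndufa2 to -0.0908.

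Long against short days (8502) gave 17789 with all probe sets, 5006 with the actin covariate, 4581 and 5337 in the arrays of each replicate number alone, and 382 and 41 at folds of at least 1.5 and 2. The difference in daily course (782) gave 271 with only the arrays compared, 1265 with a block per condition, 1187 with tissue covariates, 311 without arrays high in Gh or Prl and 85 matched by clock time. Variation under short days (1621) gave 643 with array weights, 89 with only the arrays compared, 2838 with a block per condition, 1022 without arrays high in Gh or Prl and 659 with a cosine. Variation under long days (296) gave 83 with only the arrays compared, 105 without arrays high in Gh or Prl, 492 with exchanged labels and 476 with a cosine and exchanged labels. The response to 4 h ahead of dawn (40) gave 62 with all probe sets and 4188 without subtraction of ZT16. The difference of the 4 h responses (29) gave 15 with only the arrays compared, 44 with a replicate block, 45 with a block per condition, 17 with tissue covariates, 18 with the actin covariate and 9 without arrays high in Gh or Prl; its median over all genes moved from -0.11 to -0.02 under either other scaling. The age and run contrast (8871) gave 18866 with all probe sets, 4077 with tissue covariates and 3050 at advance ZT16 alone, where Prl, Dusp4, Zbtb7a, Mtnr1a and Rpl19 did not pass. All 21 camera calls of 135 ended with an estimated correlation (0).

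Advance against delay (1592) gave 3317 with all probe sets, 934 with the actin covariate, 29, 65 and 378 at ZT0, ZT4 and ZT8 alone, 7948 with short days as baseline and 0 with advance ZT16 as its own baseline. The fit with advance ZT16 as baseline also took off the same change under short days. At ZT0 alone Per1 reversed to -0.18, Per2 to -0.0301, Zbtb16 to -0.00655 and Fkbp5 to -0.28, and at ZT8 alone Arntl to 0.0159 and Npas2 to 0.0847. With short days as baseline Malat1 reversed to -0.0173, Prl to 0.26, Vegfd to 0.0134, Tafa3 to 0.31, Dusp4 to 0.89, Arntl to 0.0702, Npas2 to 0.0806, Vgf to -0.22 and Chgb to -0.0188. With advance ZT16 as baseline Malat1 reversed to -0.11, Tmem178b to -0.18, Tafa3 to 0.0674, Dusp4 to 0.49, Arntl to 0.0661, Npas2 to 0.12, Per2 to -0.31, Prkar1a to -0.18, Col3a1 to -0.21 and Fkbp5 to -0.13. Genes shared with long days (903) were 5474 with short days as baseline, where both comparisons hold the same short-day arrays. There r across genes was 0.731. In 100 simulations of unchanged groups, with noise drawn independently for each gene, r was 0.327 to 0.393. Part of the count of 5474 is therefore expected from the shared arrays. Other settings gave 0 with advance ZT16 as baseline, where 0 first-day genes passed, and 362 with the actin covariate.

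Leaving out 1 array gave 8057 to 8720 genes for long against short days, 8007 to 9266 for age and run, 209 to 419 for variation under long days and 499 to 1456 for the difference in course. Variation under short days ran from 901 to 2765, with 1075 without ZT0 replicate 2, 924 and 2659 without ZT4 replicates 1 and 2. The response ahead of dawn ran from 18 to 334 and that after dusk from 0 to 6. The difference of the responses ran from 10 to 111: without replicate 1, 14 at short-day ZT12, 16 at short-day ZT20, 11 at advance ZT16 and 13 at delay ZT12, and without replicate 2, 18 at short-day ZT12, 14 at advance ZT16, 13 at advance ZT20, 14 at delay ZT8 and 14 at delay ZT12. Light at ZT12 and ZT16 ran from 139 to 2631: without replicate 1, 1828, 187 and 519 at short-day ZT0, ZT8 and ZT12 and 1799, 198 and 194 at delay ZT0, ZT12 and ZT16, and without replicate 2, 184 and 2089 at short-day ZT0 and ZT8 and 288, 712, 326 and 564 at delay ZT0, ZT4, ZT8 and ZT12. Advance against delay ran from 825 to 1842: without replicate 1, 977 and 842 at advance ZT4 and ZT8 and 900 and 927 at delay ZT0 and ZT8, and without replicate 2, 1053 at advance ZT4 and 857 at delay ZT4. A group left with 1 array was taken to vary like the others.

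The clock phase read from 1606 genes outside the clock list was -7.11 h under long days, -0.325 h in advance and -4.21 h in delay (SD 1.96, 1.18 and 2.33 h, 12 arrays each). Part of the long-day value comes from the earlier lights-on, as for the clock genes. The delay arrays ranged from -7.5 h to -0.1 h, with -0.1 h and -1.6 h at ZT20.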

Other observations

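No test in this part was chosen after the result was seen, except the levels of Neurod1 and Mtnr1a in the first-day conditions. The arrays were regrouped within time points in 100 ways, the real one included. For long against short days 1 gave as many genes (8502, highest other 6389). For advance against delay 1 did (1592, highest other 1368), and for age and run 1 did (8871, highest other 5923). That argues against a random split of the arrays as the source of these counts, without excluding it. Regroupings mix the conditions, so any steady difference between the sets of arrays tends to rank first, whatever its cause. For light after dusk at ZT12 and ZT16, 8 of 100 gave as many as 1111 and the highest gave 5514, so chance is not excluded. A regrouping with several times the real count points to a structure of the samples. Uneven regroupings bring back the steady difference between delay and short days that this contrast takes off, so they cannot decide about chance here.

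Neurod1 stood at 9.76 ± 0.11 (SD, n = 2) at advance ZT16 and at 6.38 to 6.83 at the other advance times, and between 6.97 and 7.26 at all 6 times in delay. Mtnr1a was at 10.47 ± 0.42 (SD, n = 2) at advance ZT12 and between 7.62 and 8.58 at the other advance times. The signs of median, mean and camera direction differed in 8 of 27 lists for advance against delay, 11 for the 4 h response ahead of dawn, 7 for light after dusk at ZT12 and ZT16 and 4 for age and run.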
